A study of Homo sapiens with 2 samples.

How the data were processed

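The data are 2 RNA sequencing libraries from HEK293 cells, an established human embryonic kidney cell line. The control group and the group labelled as overexpressing Flag-tagged ZNF184 hold 1 library each, taken from the sample titles. Per the labels' protocols, Flag-tagged ZNF184 was introduced with the XtremeGene reagent in Opti-MEM medium, RNA was extracted with Trizol, and 1.3 ug of total RNA went into each library with the NEBNext Ultra II Directional kit, which keeps the strand of the RNA. The design text of the series mentions 2 cell types, while both samples are labelled HEK293. The 2 samples carry the same transfection text, and no label says whether the control cells received an empty vector or were left untransfected. Neither cell density nor the time between transfection and harvest is given in the sources used here.

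The authors deposited a table of whole-number read counts per gene symbol for each library, with 24424 symbols in the same order and no normalization. TopHat as the aligner and hg19 as the genome build are named per the submitters' processing notes, without a version. The counting tool, the gene annotation, the handling of reads that fit several genes and whether counting used the strand are not given in the sources used here. Genes that overlap each other, antisense genes and genes with near-identical copies are for this reason uncertain. The tables hold no symbol of a mitochondrially encoded gene, so no share of mitochondrial reads was computed. No coordinates are given, because the annotation used here, GENCODE release 29, belongs to another build than the deposited counts. It was used for names, gene order, transcript length and sequence only. Of the 24424 symbols, 22583 matched a gene in it, directly or through older symbols, and 97.95% of the tested genes had a length.

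The total was 21615306 counts in the control library and 20214207 in the ZNF184 library. Counts were divided by effective library sizes from the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3 and expressed as CPM, the usual unit of counts scaled to a common library size. The log2 ratio of the ZNF184 library over the control library was computed with a prior of 1 count, scaled to each library. Genes with at least 1 CPM in at least 1 library were tested for size, 13716 of them without ZNF184. Ratios printed without a log are plain ratios of CPM with an exact 95% Clopper-Pearson interval. CPM values have an exact 95% Poisson interval. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and no replicate was sequenced. A ratio against a library at 0 is given against a floor of 3 counts per library, equal to 0.141 CPM in the control and 0.146 CPM in the ZNF184 library. The lower bound of its counting interval is given beside it. No fold is given where both libraries are at or under that floor.

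With 1 library per group there is no test between conditions, and no p-value is given. Differences are described by size, at a ratio of 2 or more or 0.5 or less, and any difference compares these libraries, not the conditions in general. The number of genes that counting error alone would put past that size was simulated in 100 pairs of libraries drawn from the pooled counts. Each of 28 gene lists fixed before the data were examined was described by the median log2 ratio of its tested members, with ZNF184 left out. That median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart below percentile 2.5 or above 97.5. Lists needed at least 3 tested members, and 27 had them. The list of mitochondrially encoded genes had none. The lists covered the processing of microRNA-7, published targets of microRNA-7, Parkinson disease genes, corepressors of KRAB zinc finger proteins, zinc finger genes, histones, stress and signalling responses, metabolism, the cell cycle, cell death and lysosomes. Further lists held neuronal markers and markers of neuroblastoma, fibroblast, leukocyte and epithelial cells.

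The genes named were set by a rule before the data were examined. It takes ZNF184, the genes of the list on the processing of microRNA-7, and the 12 genes highest and 12 lowest in the ZNF184 library by the bound of the counting interval nearest to a ratio of 1. From each list that stood apart, and from the lists on microRNA-7 targets and Parkinson disease, it takes up to 4 members by the same bound and the most abundant member. The same ranking at 10 CPM was fixed beforehand as another filter. Genes ranked at 10 CPM after leaving out read-through symbols, genes sharing sequence and symbols that start with LOC, and the groups of nuclear RNAs, chromatin regulators, FAM72 copies, stress genes, ribonuclease RNAs and KRAB corepressors, were chosen after their values were seen. Some single genes and 1 list are not reported here.

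Read-through symbols were those that join 2 known gene symbols with a hyphen. Shared sequence is the percent of 50-mers in a gene's longest transcript that also occur on the same strand in the longest transcript of another gene, and 50% or more was counted as sharing. Transcript length is that of the principal transcript in the annotation, the longest coding one where several ranked alike. Genes without a principal transcript took the longest coding transcript, or else the longest. Lists matched on length drew each member from the 50 genes outside the list nearest to it in rank of abundance and of length. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

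The steps were tested on simulated counts for this comparison over 13660 genes, with 50 genes per simulated fold. At least 2-fold was called for 2% of genes simulated at 1.5-fold, 96% at 2.5-fold, 100% at 4-fold and 100% at a ratio of 0.25, and for 0.193% of the unchanged genes. Of 200 unchanged lists of 25 genes, 3% stood apart, and 100% of 50 lists shifted by 0.3 on the log2 scale were found. The simulated counts held counting error only, with no trend by transcript length. The simulated shift was also larger than the reported median of any list that stood apart.

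Other settings chosen before the data were examined were library totals, DESeq2 1.42.0 size factors, upper quartile scaling, totals without the 10 most abundant genes, centring on mean expression with a lowess curve, no expression filter, a filter at 10 CPM, priors of 0.25 and 5 counts, thinning to equal totals, a ratio of 1.5, the whole interval beyond 2, unmatched random lists and means in place of medians. Centring on transcript length, leaving out read-through and shared-sequence genes, and matching lists on length were chosen after seeing the data. Leaving out replicates was not possible with 1 library per group. Nothing in the deposited tables was left out.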

Results

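Gene expression was measured by RNA sequencing in HEK293 cells under 2 conditions, a control and overexpression of Flag-tagged ZNF184, a zinc finger protein of the KRAB family. The study sought genes controlled by ZNF184, and its title also names microRNA-7. Each condition had 1 library, with 21615306 counts in the control and 20214207 in the ZNF184 library over 24424 gene symbols. At least 1 count was seen for 17658 symbols in the control and for 18029 in the ZNF184 library. The 10 most abundant genes held 4.20% of the counts in the control and 4.79% in the ZNF184 library. The series' own design text mentions 2 cell types although both samples are labelled HEK293. Besides ZNF184, 6 of 10236 genes at 10 CPM or more differed by 2-fold or more, a likeness that argues against 2 different cell types. The difference between the libraries has no replicate check, and the intervals given cover counting error only.

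ZNF184 itself was 544-fold higher in the library labelled as overexpressing it (95% interval 490 to 606). Its count was 349 in the control, or 16.4 CPM (14.7 to 18.2), and 183162 in the ZNF184 library, or 8923 CPM (8882 to 8964). Its share of all counts was 0.00161% in the control and 0.906% in the ZNF184 library, where it was the gene with the second highest count. None of its 50-mers occurred in the transcript of another gene. The level of ZNF184 thus matches the labels of both libraries.

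Outside the construct, few genes differed by 2-fold or more between the libraries. Of 13716 tested genes, 130 were at least 2-fold higher and 28 at least 2-fold lower in the ZNF184 library, and 98.8% lay within 2-fold. The counting interval lay above 1 for 2301 of the tested genes, below 1 for 2977 and included it for 8438. Centring the ratios on mean expression gave 85 higher and 57 lower. Simulated pairs that differed by counting error alone held 24.1 such genes on average and at most 35. Most of the 158 genes had few reads, with a median of 52 counts summed over both libraries against 1314.5 for all tested genes. Among the 10236 genes at 10 CPM or more, 5 were at least 2-fold higher and 1 at least 2-fold lower. The central 95% of ratios among these genes ran from 0.809 to 1.31. The plot of ratios by abundance shows the same narrowing towards abundant genes.

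**Figure D1:**
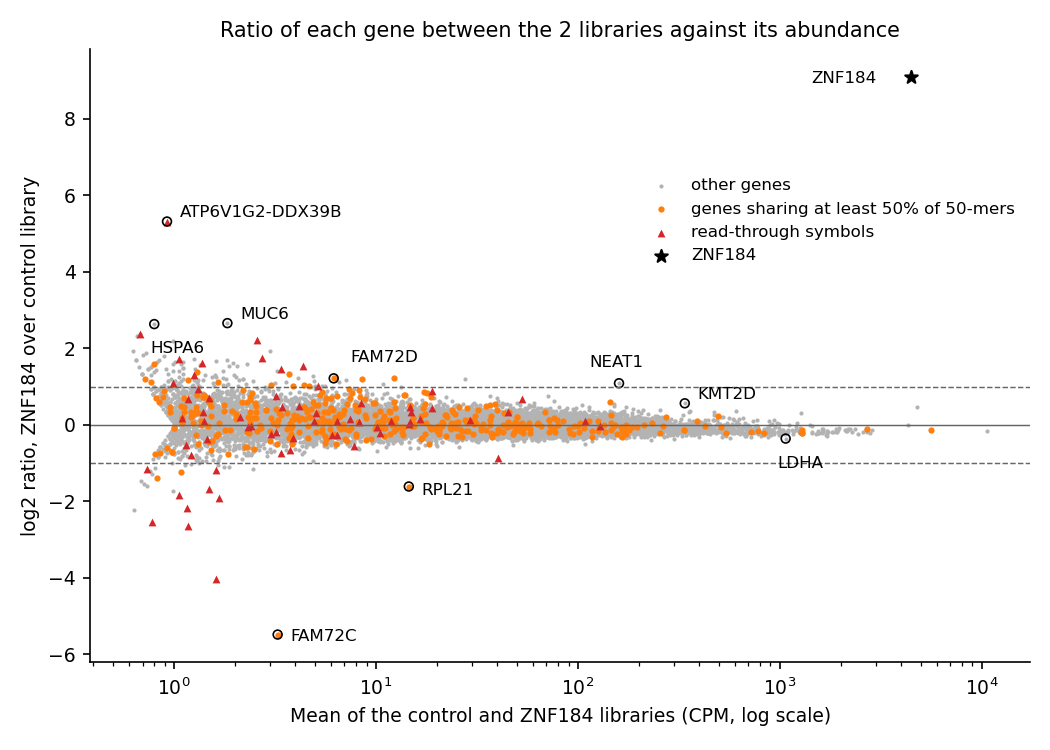
Log2 ratio of the ZNF184 library over the control library (y axis) against mean abundance in CPM on a log scale (x axis) for each tested gene, 1 library per group, with dashed lines at 2-fold. ZNF184 stands at a log2 ratio of 9.08, while 98.8% of the other genes lie within 2-fold and many of the largest ratios belong to read-through symbols (triangles) or genes that share sequence (orange).

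The genes highest in the ZNF184 library were a mixed set, many of them read-through symbols or genes with few reads. ATP6V1G2-DDX39B had 0 counts in the control and 38 in the ZNF184 library, 13.1-fold higher against the floor of 3 counts. The lower bound of its counting interval was 10.2. MUC6, a secreted gastric mucin, was 6.84-fold higher (3.50 to 14.9), with 10 and 66 counts. HSPA6, a heat-inducible HSP70 chaperone, had 4 and 29 counts, a ratio of 7.52 (2.64 to 29.4). It shares 45.5% of its 50-mers with another gene. PLIN4, a lipid droplet coat protein, was 3.91-fold higher (2.51 to 6.28). The scavenger receptor gene STAB1 had 4 and 24 counts and TMEM212 had 4 and 23. HOXA10-HOXA9 was 4.80-fold higher (2.90 to 8.35), TMX2-CTNND1 3.47-fold (2.22 to 5.60), DYX1C1-CCPG1 2.93-fold (2.09 to 4.18) and ZNF559-ZNF177 6.22-fold (2.14 to 24.7). The uncharacterized genes LOC101928841, at 5.04-fold (2.20 to 13.5), and LOC100190986, at 2.30-fold (2.02 to 2.61) with 356 and 788 counts, completed the 12.

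At the other end, FAM72C had 137 counts in the control and 2 in the ZNF184 library, a ratio of 0.0151 (0.00181 to 0.0557). It belongs to a family of near-identical gene copies and shares 95.02% of its 50-mers with another gene. Its copy FAM72D, named after its values were seen, went the other way with 79 and 178 counts. Summed over the 4 FAM72 copies, the ratio was 0.928 (0.822 to 1.05). RPL21, which codes for a protein of the large ribosomal subunit and has many pseudogenes, had 468 and 147 counts, a ratio of 0.326 (0.269 to 0.393), and 57.4% of its 50-mers are shared. The other low genes were ZFP91-CNTF at 0.0471 (0.00948 to 0.144), HSPE1-MOB4 at 0.141 (0.0492 to 0.333), TGIF2-C20orf24 at 0.143 (0.0365 to 0.407), TRIM39-RPP21 at 0.202 (0.0819 to 0.437), IPO11-LRRC70 at 0.255 (0.131 to 0.463), CORO7-PAM16 at 0.259 (0.110 to 0.548), TMEM256-PLSCR3 at 0.296 (0.151 to 0.545) and RPL36A-HNRNPH2 at 0.546 (0.493 to 0.604). The bitter taste receptor gene TAS2R14 had 23 and 4 counts, and the long noncoding RNA gene GBAT2 had 33 and 9.

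Of the 24 genes named by this ranking, 15 were read-through symbols or shared at least 50% of their 50-mers. Several single genes that form the read-through symbols lay near a ratio of 1. HOXA9 was at 0.940 (0.877 to 1.01), DDX39B at 0.931 (0.904 to 0.958), ZFP91 at 1.02 (0.971 to 1.07), IPO11 at 1.03 (0.963 to 1.104) and CTNND1 at 0.967 (0.924 to 1.01). Others lay further off, such as CNTF with 19 and 45 counts at 2.46 (1.41 to 4.45), ZNF177 with 33 and 13 counts at 0.408 (0.197 to 0.797) and DYX1C1 with 65 and 40 counts at 0.638 (0.419 to 0.961), each opposite in direction to its read-through symbol. HOXA10 at 0.853 (0.801 to 0.908) and TRIM39 at 1.19 (1.03 to 1.38) were also opposite to theirs. HSPE1 at 0.756 (0.726 to 0.787), PAM16 at 0.799 (0.705 to 0.906) and RPL36A at 0.871 (0.854 to 0.889) went the same way as their read-through symbols. So did RPP21 at 0.843 (0.730 to 0.973) and TMEM256 at 0.832 (0.742 to 0.934).

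The ranking at 10 CPM or more shared 3 genes with the first, LOC100190986, RPL21 and RPL36A-HNRNPH2. NEAT1, the nuclear long noncoding RNA that builds paraspeckles, was 2.12-fold higher in the ZNF184 library (2.02 to 2.24), with 2182 and 4467 counts. MDM4, a negative regulator of p53, was 1.69-fold higher (1.57 to 1.83), the zinc finger gene ZNF460 1.93-fold (1.53 to 2.44), and LINC01004 2.12-fold (1.73 to 2.59). The small RNA genes RPPH1 and RMRP, RNA subunits of ribonucleases P and MRP, were at 2.30 (1.83 to 2.91) and 1.82 (1.56 to 2.13). PMS2P9, at 2.32 (1.92 to 2.82), and NPIPB3, at 1.80 (1.55 to 2.09), are copies within gene families, and RPPH1, RMRP, PMS2P9 and NPIPB3 each share over 50% of their 50-mers. PFN1P2 was at 1.99 (1.66 to 2.38) and LOC100505915 at 1.89 (1.52 to 2.36). Besides RPL21 and RPL36A-HNRNPH2, those below a ratio of 1 included DUT, the dUTPase that keeps uracil out of DNA, at 0.707 (0.666 to 0.751), the histone variant gene H3F3A at 0.619 (0.506 to 0.756), and H2AFX, the histone variant phosphorylated at DNA breaks, at 0.742 (0.701 to 0.785). H3F3A had 268 and 160 counts and shares 12.9% of its 50-mers with another gene. HSPE1, the mitochondrial chaperonin HSP10, was at 0.756 (0.726 to 0.787) and LDHA, lactate dehydrogenase A, at 0.779 (0.765 to 0.794). HSPB11, C8orf59, FAM229B, KRT10 and NUDT16L1 lay between 0.660 for KRT10 and 0.699 for C8orf59.

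Genes at 10 CPM or more not known to share sequence, picked after their values were seen, added several regulators. KMT2D, a histone H3 methyltransferase of enhancers, was 1.48-fold higher (1.43 to 1.53) and the transcription factor gene CREB5 1.62-fold (1.47 to 1.79). KCNQ1OT1, an imprinted antisense RNA, was at 1.68 (1.51 to 1.86), IGSF9B at 1.85 (1.47 to 2.32), the neutral amino acid transporter gene SLC1A4 at 1.67 (1.40 to 2.003) and ZNF70 at 1.63 (1.41 to 1.88). BAIAP3, FAM227A, LINC00504 and MCM3AP-AS1 lay between 1.76 and 1.79, and LINC01000, for which shared sequence was not determined, was at 1.54 (1.44 to 1.66). Lower were the ion channel gene TMEM38B at 0.744 (0.688 to 0.804), the mitochondrial ribosomal gene MRPL20 at 0.7501 (0.702 to 0.801), BNIP3, a mitophagy receptor gene induced by hypoxia, at 0.755 (0.706 to 0.808), ZNHIT2 at 0.697 (0.599 to 0.809) and RAB30-AS1 at 0.643 (0.513 to 0.802). KCNQ1OT1 and MCM3AP-AS1 lie on the strand opposite to KCNQ1 and MCM3AP, and their values are uncertain while the strand setting of the counting is not given.

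Genes of the processing of microRNA-7 differed little between the libraries. The RNA binding protein gene ILF2 was at 0.877 (0.853 to 0.900) and HNRNPK, whose intron hosts a microRNA-7 precursor, at 0.883 (0.867 to 0.899). The microRNA processing genes DICER1, DROSHA and AGO2 were at 1.16 (1.101 to 1.22), 1.14 (1.07 to 1.20) and 1.17 (1.06 to 1.29). TARBP2 was at 0.895 (0.805 to 0.996), while the intervals of DGCR8, XPO5, ELAVL1, MSI2 and QKI included 1. The transcripts of DICER1, DROSHA and AGO2 are 10331, 5305 and 14581 nt long, and those of ILF2, HNRNPK and TARBP2 1659, 2942 and 1867 nt. Across genes, longer transcripts tended to have higher ratios, so these directions cannot be told apart from that trend. MIR7-3HG, a host gene of microRNA-7, had 2 counts in the control and 0 in the ZNF184 library, too few for a fold. CDR1 had 79 and 101 counts, a ratio of 1.33 (0.978 to 1.80), and no symbol for its antisense RNA was matched. Mature microRNA-7 was not measured by these libraries.

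The 24 measured targets of microRNA-7 had a median log2 ratio of 0.00 at percentile 83.4 of matched random lists, with 4 intervals above 1, 8 below and 12 including it. Among them the growth factor receptor gene IGF1R was at 1.24 (1.16 to 1.32), IRS2, an adaptor of insulin signalling, at 1.28 (1.097 to 1.49), the DNA repair gene XRCC2 at 1.34 (1.23 to 1.46) and the mitochondrial channel gene VDAC1 at 0.890 (0.862 to 0.919). The transcripts of IGF1R and IRS2 are 12235 and 8138 nt long, where ratios of all genes tended to be above 1. Those of XRCC2 and VDAC1 are 3067 and 1953 nt long, where ratios tended to be below 1. PARP1, the most abundant, was at 0.925 (0.912 to 0.939), a direction that flipped with centring on mean expression. The 24 Parkinson disease genes had a median of -0.01 at percentile 64.9, with 2 intervals above 1, 7 below and 15 including it. The oxidative stress protein gene PARK7 was at 0.852 (0.817 to 0.887), UCHL1 at 0.846 (0.810 to 0.884), CHCHD2 at 0.856 (0.829 to 0.885) and VPS13C at 1.16 (1.05 to 1.28). PARK7, UCHL1 and CHCHD2 have transcripts of 1088, 1172 and 901 nt, and VPS13C of 13300 nt. Across genes, short transcripts tended to be lower and long ones higher, so these directions cannot be told apart from that trend. EIF4G1, the most abundant, was at 0.949 (0.931 to 0.967) and flipped likewise.

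Among the 27 lists with enough members, 7 stood apart from random lists of like abundance, where 1.35 would if genes varied independently. Genes of a list can vary together between 2 preparations, so the number to be met by chance is not known. Target genes of ATF4, the transcription factor of the integrated stress response, were higher in the ZNF184 library. Their median log2 ratio was 0.11 against -0.12 to 0.01 for the central 95% of matched lists, at percentile 100. Of 31 members, 15 had an interval above 1, 3 below and 13 including it. CHAC1, which degrades glutathione, was 1.80-fold higher (1.29 to 2.54), the cystine transporter gene SLC7A11 1.42-fold (1.29 to 1.57) and the secreted hormone gene STC2 1.23-fold (1.16 to 1.32). ATF4 itself was at 1.08 (1.06 to 1.11), and DDIT4, an inhibitor of mTOR signalling, went the other way at 0.789 (0.744 to 0.837).

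Zinc finger genes with a ZNF symbol, without ZNF184, were also slightly higher, with a median log2 ratio of 0.08 over 430 genes at percentile 100. Their intervals lay above 1 for 98 genes, below for 17 and included it for 315. ZNF462 was 2.25-fold higher (1.75 to 2.91) and ZNF121 1.59-fold (1.35 to 1.88), beside ZNF460 and ZNF70, while the most abundant, ZNF703, was at 1.02 (0.987 to 1.05). The 10 measured targets of NF-kB, a transcription factor of inflammation, had a median of 0.24 at percentile 97.6, with 5 intervals above 1, 1 below and 4 including it. The subunit gene RELB was 1.49-fold higher (1.08 to 2.06), BCL3 1.47-fold (1.04 to 2.08), the feedback inhibitor gene TNFAIP3 1.38-fold (1.09 to 1.76) and REL, which shares 50.6% of its 50-mers with another gene, 1.252-fold (1.104 to 1.42). NFKB1, the most abundant, was at 0.987 (0.892 to 1.09). This list no longer stood apart at 10 CPM, where its median was 0.07, and under 6 other settings.

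Lower lists held genes of energy metabolism, translation and DNA replication. Nuclear-encoded genes of the respiratory chain had a median log2 ratio of -0.22 over 78 genes, with 72 intervals below 1, 0 above and 6 including it. COX6C was at 0.773 (0.723 to 0.826), UQCRQ at 0.792 (0.744 to 0.844), COX7C at 0.801 (0.768 to 0.835), NDUFB10 at 0.801 (0.766 to 0.839) and the most abundant, the ATP synthase gene ATP5B, at 0.848 (0.832 to 0.865). Cytosolic ribosomal protein genes had a median of -0.20, and all 76 intervals lay below 1 with TMM scaling. RPS21 was at 0.780 (0.752 to 0.808), RPS12 at 0.791 (0.770 to 0.811), RPS27A at 0.796 (0.780 to 0.813) and RPS2, the most abundant, at 0.911 (0.904 to 0.919), above 1 once ratios were centred on expression or length. Both lists were at percentile 0. The medians came closer to 0 when ratios were centred on mean expression, at -0.17 for the respiratory chain and -0.07 for ribosomal proteins, or on transcript length, at -0.07 and -0.05.

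Genes of hypoxia and glycolysis had a median log2 ratio of -0.14 at percentile 0.42, with 15 of 29 intervals below 1 and 0 above. LDHA and BNIP3 were the lowest by their bounds, followed by the glycolytic genes PGK1 at 0.796 (0.775 to 0.818) and PGAM1 at 0.804 (0.785 to 0.822), and GAPDH, the most abundant, was at 0.872 (0.862 to 0.883). The list was inside the matched range at 10 CPM, with a median of -0.13. S phase genes had a median of -0.14 at percentile 0.57, with 17 of 26 intervals below 1 and 0 above. The replicative helicase genes MCM6 and MCM5 were at 0.804 (0.774 to 0.835) and 0.819 (0.787 to 0.853), MCM7 at 0.885 (0.863 to 0.907), GINS2 at 0.805 (0.753 to 0.860), and PCNA, the sliding clamp of DNA polymerases, at 0.831 (0.798 to 0.866).

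**Figure D2:**
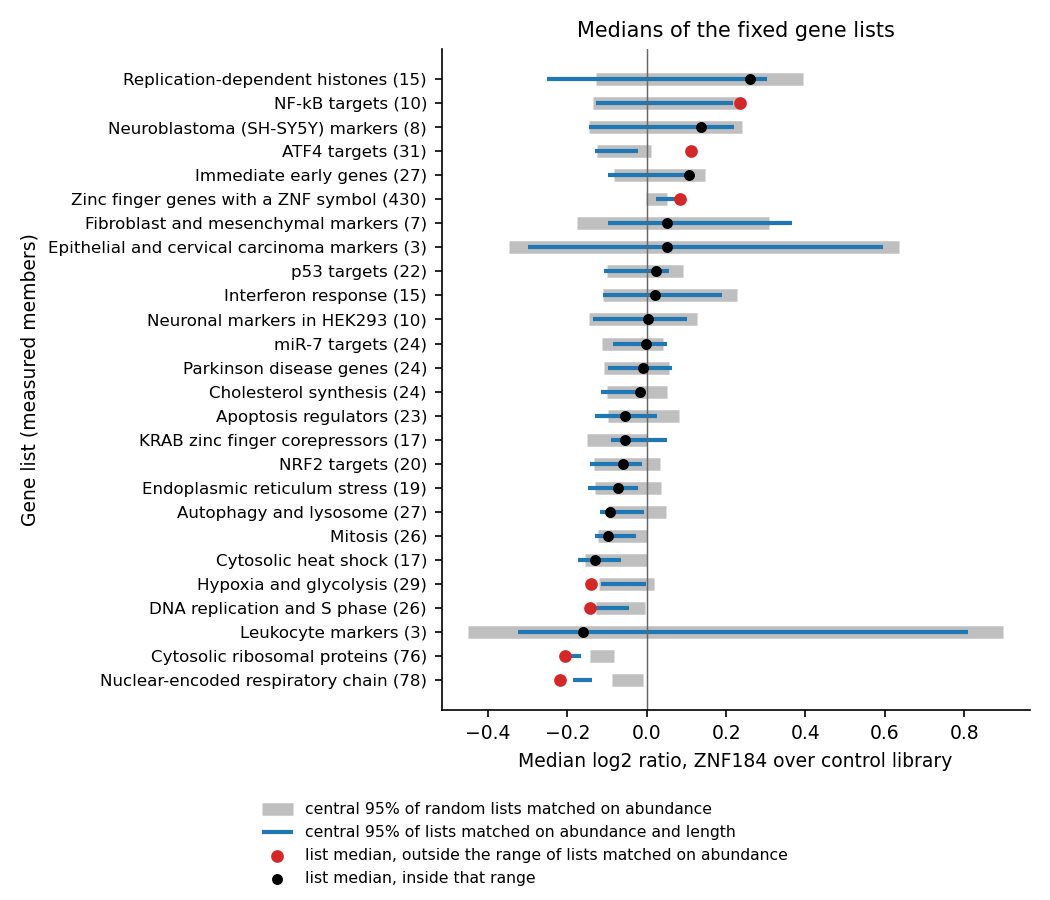
Median log2 ratio of the ZNF184 library over the control library (x axis) for gene lists with at least 3 measured members (y axis, members in brackets), with the central 95% of random lists matched on abundance (grey) or on abundance and length (blue). The respiratory chain lies at -0.22 and ATF4 targets at 0.11, outside both ranges, and ribosomal proteins at -0.20, where the blue range comes from less abundant genes.

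The ratios followed transcript length. Across the 10156 genes at 10 CPM or more with a length, Spearman's rho was 0.51 and Pearson's r with log2 length 0.47, where genes are not independent replicates. In the eighth of these genes with the shortest transcripts, at a median of 1155 nt, the median ratio was 0.889. The eighth with the longest, at a median of 8745.5 nt, had a ratio of 1.09. GC content showed no such relation, with a rho of 0.01. Ribosomal protein genes had a median length of 1010.5 nt and respiratory chain genes 1119.5 nt. Random lists matched on abundance and length had a median of -0.16 for the respiratory chain. For ribosomal proteins they had -0.18, but the genes near them in length had a median of 345 CPM against 904 for the list, so abundance was not matched there. The other 6 lists that stood apart still lay outside the central 95% of such lists, and the immediate early genes, with a median of 0.11 at percentile 97.8, joined them.

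**Figure D3:**
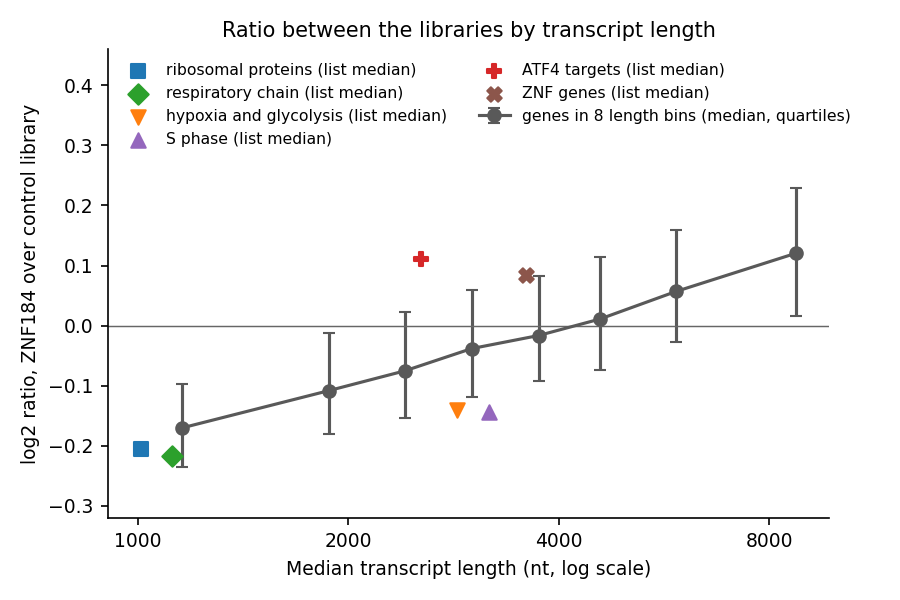
Median log2 ratio of the ZNF184 library over the control library (y axis) against median transcript length in nt on a log scale (x axis), for genes at 10 CPM or more in 8 bins of length (circles, bars from the first to the third quartile) and for 6 gene lists (other symbols, medians). The bins go from -0.17 for the shortest to 0.12 for the longest transcripts.

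The other lists lay within the range of random lists of like abundance, although immediate early genes, histones, autophagy, heat shock and mitosis left it under some other settings. Corepressors of KRAB zinc finger proteins had a median log2 ratio of -0.06 at percentile 71.7, with TRIM28, their scaffold, at 0.912 (0.891 to 0.932) and the methyltransferase gene SETDB1 at 1.11 (1.03 to 1.20). Cytosolic heat shock genes had a median of -0.13 at percentile 11.7 and a mean of 0.04, opposite in sign. Genes of endoplasmic reticulum stress were at -0.07 (percentile 34.4), NRF2 targets at -0.06 (42.2) with a mean of 0.02, interferon response genes at 0.02 (37.2) and p53 targets at 0.02 (74.3). Replication-dependent histones, with 15 measured genes, were at 0.26 (84.8). Cholesterol synthesis was at -0.02 (60.9), mitosis at -0.10 (15.6), apoptosis regulators at -0.05 (15.8), and autophagy and lysosome genes at -0.09 (3.30). Neuronal markers were at 0.00 (63.3).

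Markers of other cells also lay within that range. Neuroblastoma markers had a median log2 ratio of 0.14 at percentile 84.9 over 8 measured genes of 18, fibroblast and mesenchymal markers 0.05 at percentile 52.4 over 7 of 14, leukocyte markers -0.16 at percentile 15.2 over 3 of 14, and epithelial markers 0.05 at percentile 42.5 over 3 of 12. In the first of these lists 1 interval lay above 1 and 7 included it.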

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

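Centring on transcript length, leaving out read-through and shared-sequence genes, and matching lists on length were chosen after seeing the data. The ratio of ZNF184 was 540 to 566 under the 4 other scalings, of which totals without the 10 most abundant genes was added for this ratio after seeing the data. Its log2 ratio was 9.29 with centring on mean expression, above the counting interval of 8.94 to 9.24, because centring subtracts the fitted trend at its abundance. Counts of genes at 2-fold stayed within 1.5 times the reported 130 and 28 under all other scalings, both priors, thinning and centring on length. With centring on mean expression they were 85 higher and 57 lower. Without an expression filter they were 1799 and 462, since genes with few counts enter, and at 10 CPM they were 5 and 1, since fewer genes are tested. A ratio of 1.5 gave 502 and 130, and requiring the whole interval beyond 2 gave 13 and 7. Without read-through and shared-sequence genes 15 were lower, since 13 of the 28 were left out. Of the 24 genes ranked highest and lowest, 12 stayed among them without a filter, 3 at 10 CPM and 9 without read-through and shared-sequence genes.

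Unmatched random lists put 11 lists apart in place of 7, adding immediate early genes (0.11), replication-dependent histones (0.26), cytosolic heat shock (-0.13) and mitosis (-0.10). Immediate early genes also stood apart at 10 CPM (0.11), centred on length (0.16) and matched on length (0.11), histones when thinned (0.41), and autophagy and lysosome genes by their mean (-0.08). The cause was not tested. ATF4 targets ranged from 0.08 to 0.17, zinc finger genes from 0.06 to 0.14, the respiratory chain from -0.23 to -0.07, ribosomal proteins from -0.22 to -0.05 and S phase from -0.15 to -0.08, each standing apart under all 15 alternatives, of which matching on length drew less abundant genes for ribosomal proteins. NF-kB targets fell inside the range in 7 of 15, with medians of 0.28 (library totals), 0.32 (no filter), 0.074 (10 CPM), 0.22 (thinned), 0.21 (centred on length) and 0.15 (without shared-sequence genes), and a mean of 0.24. Hypoxia and glycolysis did so at 10 CPM, at -0.13, and ranged from -0.17 without a filter to -0.08 centred on mean expression. The cause was not tested.

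Centring on mean expression reversed EIF4G1 (0.063), PARP1 (0.049) and RPS2 (0.081), and centring on length RPS2 (0.023). Centring subtracts the fitted trend, which can turn a slightly negative value positive for an abundant gene or a short transcript. The cause of the trends was not tested. Of 1589 values of 133 named genes under alternatives, 1471 stayed inside the counting interval. Leaving out a replicate and a paired fit were not possible with 1 library per group. Depth limits genes under 3 counts, such as MIR7-3HG.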

Other observations

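The groups of genes described here were chosen after their values were seen. A set of 3 nuclear-retained RNAs was higher in the ZNF184 library, with NEAT1 at 2.12 (2.02 to 2.24), KCNQ1OT1 at 1.68 (1.51 to 1.86) and MALAT1 at 1.38 (1.32 to 1.45). Several genes of large chromatin regulators were higher too, picked for their values and not counted against other such genes. Besides KMT2D, the methyltransferase genes KMT2C and KMT2A were at 1.37 (1.28 to 1.47) and 1.24 (1.18 to 1.30), the acetyltransferase gene CREBBP at 1.26 (1.20 to 1.32), the remodeller genes CHD7, EP400 and SRCAP at 1.23 (1.16 to 1.30), 1.22 (1.16 to 1.28) and 1.17 (1.14 to 1.21). SRCAP shares 85.4% of its 50-mers with another gene. The transcripts of these 7 genes are 10803 to 19419 nt long and those of the 3 nuclear RNAs 8708 to 91667 nt, in the range where the median ratio of all genes was above 1.

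Among genes of acute stress, JUN was at 1.31 (1.26 to 1.37), the heme oxygenase gene HMOX1 at 1.37 (1.27 to 1.49), DDIT3, the stress factor CHOP, at 1.47 (1.12 to 1.94), ATF3 at 1.32 (1.15 to 1.51), GADD45A at 1.18 (1.06 to 1.33), and GADD45B at 1.09 (0.907 to 1.32), with an interval that includes 1. DDIT3 and ATF3 are also members of the ATF4 list, so their values and that list are not separate evidence. Of the fixed lists of stress and related responses, ATF4 and NF-kB targets stood apart as higher, and hypoxia and glycolysis as lower. Immediate early genes, NRF2 targets, heat shock and endoplasmic reticulum stress lay within the range of random lists of like abundance. Immediate early genes left that range when lists were matched on length too. Next to ZNF184 in the gene order of the reference, the zinc finger gene ZNF391 had 113 and 124 counts (ratio 1.14, 0.875 to 1.48) and the pseudogene ZNF204P 559 and 705 (1.31, 1.17 to 1.46). Genes with very low expression had slightly more counts in the ZNF184 library. The 10% of tested genes lowest in abundance had a median log2 ratio of 0.18 against -0.09 for the 10% highest, and 6766 and 6395 symbols were at 0. The 376 olfactory receptor symbols held 30 counts in the control and 40 in the ZNF184 library, too few to tell apart from counting error.

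The tests of transcript length, of the construct and of transfection in the next paragraphs were chosen after the result was seen, while those of single members, of shared sequence and of counting error were set before.

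Lists of the respiratory chain, ribosomal proteins, hypoxia and glycolysis, and S phase were lower and zinc finger genes higher in the ZNF184 library. A difference between the libraries linked to transcript length, as RNA integrity or library preparation could give, is a candidate explanation. Matched on annotated length as well as abundance, the medians stayed at percentile 0 for the respiratory chain, 0.23 for hypoxia and glycolysis, 0.28 for S phase and 99.8 for zinc finger genes. This argues against annotated length as the whole cause, although matched lists reached -0.16 of the respiratory chain's -0.22, -0.06 of -0.14 for hypoxia and glycolysis, -0.09 of -0.14 for S phase and 0.05 of 0.08 for zinc finger genes. Annotated lengths can differ from those of the transcripts in the cells, so a remainder left by inexact matching is not excluded. For ribosomal proteins, at percentile 0.25, length cannot be told apart from another cause, because the genes nearest in length were less abundant, at 345 against 904 CPM. An effect of the ZNF184 construct on these groups stays open, since with 1 library per group it cannot be told apart from a difference between preparations.

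ATF4 targets were higher against the trend of their length. Lists matched on length and abundance had a median of -0.08 where ATF4 targets had 0.11, at percentile 100. The list does not rest on a few members, as 15 of its 31 intervals lay above 1, 3 below and 13 included it. The median without its 5 highest genes was 0.05 against -0.11 for random lists treated alike, also at percentile 100. A median is little moved by a few members, so dropping them adds little. A response to transfection and not to ZNF184 may account for the higher ATF4 targets as well, and 0 libraries were labelled as transfected with an empty vector, so the 2 cannot be told apart. A stress response tied to ZNF184 remains a hypothesis, which replicate libraries with an empty-vector control would test.

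Many of the largest ratios belonged to read-through symbols, gene copies and genes with few reads, while NEAT1, with 2182 and 4467 counts, and LOC100190986, with 356 and 788, were also past 2-fold. Shared sequence was not determined for LOC100190986. Of the 158 genes at 2-fold, 12.7% were read-through symbols against 0.474% of all tested genes, and of the 146 with a shared-sequence value 23.97% shared at least 50% of their 50-mers, against 3.54% of the 13435 tested genes with one. Simulated pairs that differed by counting error alone held as many genes in 0 of 100 cases, which decides nothing about the cause, since separately prepared libraries differ by more than counting error. Reads divided differently between gene models that share sequence are a candidate explanation for part of the pattern. The SD of log2 ratios of genes sharing at least 50% was 1.93 times that of genes with little shared sequence at like abundance (1.48 to 2.33 in 1000 resamples). The sharing genes include those with the largest ratios, so this SD restates the pattern and does not show its cause. Another 120 of the 158 genes are not known to be read-through symbols or to share at least 50%, those without a shared-sequence value among them. No other explanation was tested for these.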
